A study of Mus musculus with 12 samples.

How the data were processed

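RNA was measured in 12 libraries of 4T1 cells, a mammary carcinoma line of BALB/c mice. The libraries form 6 groups of 2, from 3 cell lines each with vehicle or with interferon gamma (IFN-gamma) for 24 hours at 20 ng/ml. The cell lines carried a guide against the Rosa26 locus (control) or either of 2 guides against Cebpd, named sgRNA1 and sgRNA2. Groups were taken from the sample titles and the treatment entry of the labels, since the treatment protocol names IFN-gamma for all samples of the series. Per the labels' protocols, libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. That kit does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

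The authors deposited whole-number read counts per gene, not normalized. The submitters' processing notes name STAR 2.4.0, HTSeq without a version, DESeq2 1.10 and the mouse build mm10, without saying which step each was used for. The annotation, the strand setting of the counting and any filter are not given in the sources used here. Gene names were matched to GENCODE vM21 on GRCm38, the same assembly as mm10. Of 16283 genes in the table, 15941 had that name in the annotation, 259 matched through a synonym and 83 had no match. Listed genes were also matched through synonyms, except where both names are current symbols of different genes. Coordinates are 1-based. Near-identical copies can share reads, so values for Tgtp1 and Tgtp2, the Gbp, Oas, Serpina3, Prl3d, Raet1 and H2 families, and Ifit3 are uncertain to that extent. The H2 genes differ in sequence between BALB/c mice and the C57BL/6 reference, which can also lower or shift their counts.

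Total counts per library lay between 16912710 and 24784371. Genes were kept with edgeR's filterByExpr over the 6 groups (minimum count 10, minimum total 15), which left 13601 genes holding 99.965% of all counts. The other 2682 genes were not tested, 7 of them at 0 in all libraries. Library sizes were scaled by TMM, with factors from 0.963 to 1.09. CPM values were computed from the deposited counts and these scaled sizes, and are given as the mean ± SD of 2 libraries unless stated otherwise. The chi-square per degree of freedom between the 2 libraries of a group was 2.77 to 7.28, so no pair differed by less than sampling noise, and each library was counted separately. The Spearman correlation across genes within groups was 0.996 to 0.9975. Residual degrees of freedom were 6, and the common biological coefficient of variation was 4.67%.

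Differences were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in a model with a term for each of the 6 groups fitted to all 12 libraries. A gene was called at an adjusted p below 0.05. The comparisons were knockout against control in vehicle and in IFN-gamma, IFN-gamma against vehicle in control and in knockout, and their difference (the interaction). In each, the mean of the 2 guides on the log scale stood for the knockout. Each guide was also tested alone, and the guides against each other. Log2 fold changes are given ± SE, with SE computed from the fold change and its F statistic. This SE restates the test and is not a direct measure of the error of the fold change. For large changes from few counts in 1 arm, such as those of Gbp4 and Cxcl9 with IFN-gamma, it is smaller than the counting error. For genes without a count in 1 arm, a bound was computed against a floor of 3 counts per library. For genes with 1 to 3 counts there, the ratio is given with its 95% counting interval. Such bounds and intervals cover counting error only.

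Gene lists were fixed before the data were examined, and tested with limma's camera on the same fit at a preset correlation of 0.01. Camera was repeated with an estimated correlation, and fry was run as an alternative. List p-values were adjusted over the lists within each comparison. Member counts adjusted over the list alone equal those over all genes tested wherever no second count is given. The lymphocyte and erythroid lists had no tested member and were not analysed here. The genes named in the text were also chosen by a rule fixed in advance. The rule takes Cebpd and, per comparison, up to 8 rises and 8 falls, the largest in fitted fold change. They come from called genes with a mean of at least 1 CPM over all 12 libraries and the same sign with each guide. As this mean includes the IFN-gamma libraries, genes raised by IFN-gamma passed more readily, also in the vehicle comparison and the interaction. Rises of similar size in vehicle, such as Cbr3 (7.60) and Wnt11 (7.15), were left out by this limit. In the knockout comparisons and the interaction, the genes taken also had an unadjusted p below 0.05 with each guide. Except for the interaction, every library of 1 arm had to lie above every library of the other. From each described list, up to 4 members with the smallest p are named. Gene models without a proper symbol were passed over. List members that went against the direction of their list are named after their values were seen. Values of some genes that the rule takes are not reported here, although these genes stay in the counts and tests of their lists.

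The alternatives, all fixed before the data were examined, were DESeq2's size factors, upper quartile and plain library totals in place of TMM, no filter on low counts, a filter at 1 CPM on average, DESeq2's Wald test, limma voom, a fit to only the groups named, the replicate number as a block, a joint knockout group per treatment, each guide alone, and leaving out each library in turn. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

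The test was run on simulated counts with 200 changed genes. These were drawn from genes with a mean of at least 1 CPM, so recovery of rarer genes was not measured. Of genes changed 2-fold, it recovered 97.0% for knockout in vehicle (13252 genes tested, 19 false calls) and 91.0% for knockout in IFN-gamma (13224 genes, 14 false calls). It recovered 89.6% for IFN-gamma in control (13240 genes, 11 false calls), 92.5% for IFN-gamma in knockout (13232 genes, 19 false calls) and 83.6% for the interaction (13227 genes, 16 false calls). At 1.5-fold the shares were 89.6%, 83.6%, 82.1%, 88.1% and 70.1% in the same order. In each comparison of this run, false calls made up more of the calls than the nominal 0.05.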

Results

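RNA sequencing was applied to 4T1, a BALB/c mammary carcinoma line used as a model of triple-negative breast cancer, with Cebpd intact or targeted by CRISPR guides. Cebpd encodes C/EBPδ, a basic leucine zipper transcription factor of acute phase and inflammatory genes. The series asks how the transcriptome differs without Cebpd and how it responds to IFN-gamma, a cytokine that signals through JAK1 and JAK2. Control libraries carried a guide against Rosa26, a locus used as a neutral target, and the libraries labelled Cebpd knockout carried sgRNA1 or sgRNA2. Each of the 6 groups had 2 libraries. Total counts in vehicle were 19574686 and 19244015 in control, 20221146 and 16912710 with sgRNA1, and 19873018 and 18304354 with sgRNA2. In IFN-gamma they were 21485951 and 20165003 in control, 19696592 and 18435431 with sgRNA1, and 18625885 and 24784371 with sgRNA2. Mitochondrially encoded mRNAs took 0.67% and 0.62% of counts in control vehicle libraries, 0.814% and 0.839% with sgRNA1 and 1.12% and 1.14% with sgRNA2. In IFN-gamma their shares were 1.03% and 1.18% in control, 0.544% and 0.54% with sgRNA1, and 0.628% and 0.533% with sgRNA2. Cytosolic ribosomal protein mRNAs took 8.51% and 8.62% in control, 11.2% and 11.3% with sgRNA1 and 13% and 13.5% with sgRNA2 in vehicle, and in the same order 7.6% and 7.59%, 7.55% and 7.1%, and 11.2% and 10.2% in IFN-gamma.

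Cebpd mRNA was present in all 12 libraries, and its level did not separate the libraries labelled knockout from control in vehicle. Control vehicle libraries had 176 and 136 counts (8.11 ± 1.39 CPM), those with sgRNA1 271 and 222 (13.5 ± 0.172 CPM), and those with sgRNA2 204 and 150 (9.54 ± 1.46 CPM). After IFN-gamma the counts were 1106 and 956 in control (51.3 ± 3.07 CPM), 980 and 918 with sgRNA1 (45.8 ± 0.211 CPM), and 563 and 749 with sgRNA2 (29.8 ± 0.591 CPM). Cebpd was thus higher in the knockout-labelled libraries in vehicle (log2 fold change 0.49 ± 0.11, edgeR adjusted p = 0.000672) and lower in IFN-gamma (-0.47 ± 0.07, adjusted p = 1.37e-05). IFN-gamma raised it by 2.66 ± 0.10 in control and 1.70 ± 0.07 in knockout-labelled cells, and the interaction was -0.96 ± 0.13 (adjusted p = 3.75e-06). With a joint knockout group per treatment the knockout differences were 0.51 (adjusted p = 0.133) and -0.44 (adjusted p = 0.163), and the interaction was -0.95 (adjusted p = 0.0644). By guide, the vehicle difference was 0.74 ± 0.12 for sgRNA1 and 0.24 ± 0.13 for sgRNA2 (adjusted p = 0.1), and the IFN-gamma difference was -0.17 ± 0.08 (adjusted p = 0.092) and -0.79 ± 0.09. Cebpd (ENSMUSG00000071637.5) lies on chromosome 16 from 15887286 to 15891031, plus strand. Its main transcript has 1 exon, with the coding sequence from 15887325 to 15888128 and the 3′ UTR from 15888129 to 15891031. The target sites of the guides are not given in the sources used here, and counts over the whole gene do not show whether a small edit was made. The Cebpd mRNA level therefore neither bears out nor contradicts the label, and the groups below are named as labelled.

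**Figure D1:**
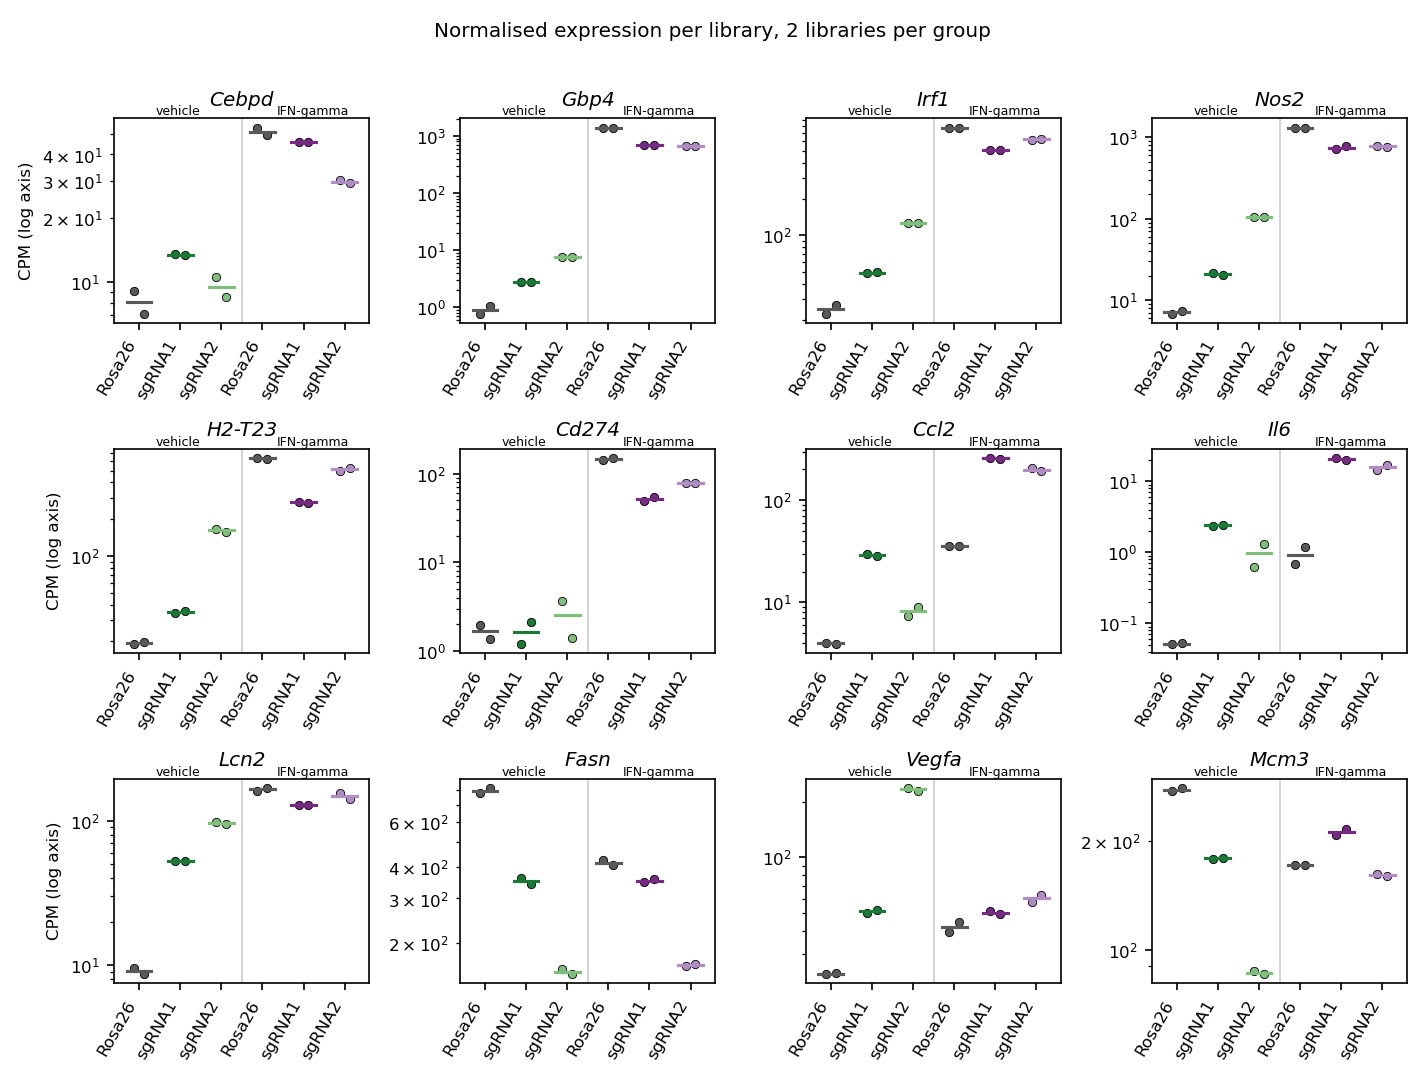
Expression of 12 genes in each of the 12 libraries, in CPM on a log axis (linear near 0 where values reach it), by guide and treatment, with lines at the mean of 2 libraries. The genes shown were chosen after their values were seen, and Nos2 rose with IFN-gamma from 7.16 to 1310 CPM in control cells.

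In control cells, IFN-gamma raised the genes of its own response. All 38 tested members of the interferon gamma response list rose, with a median log2 fold change of 8.33, or 7.92 with genes at 0 set to their bound (camera adjusted p = 2.89e-206, and 6.3e-06 with an estimated correlation). Cxcl9, a chemokine that attracts T cells through CXCR3 (chromosome 5, 92321347 to 92328079), had no count in either vehicle library and 398.5 ± 16.1 CPM after IFN-gamma, at least 2550-fold higher. The GTPase gene Tgtp2 rose at least 702-fold to 109.6 ± 0.0533 CPM, the transcription factor gene Batf2 at least 337-fold to 52.7 ± 0.164 CPM, and Apol6 at least 310-fold to 48.4 ± 1.07 CPM. Tgtp1, an interferon-inducible GTPase gene, rose by a ratio of 12200 (95% counting interval 2190 to 483000), Gbp10 by 6130 (2100 to 29700), Gbp5 by 4630 (1280 to 38200) and Iigp1 by 3870 (1320 to 18700). Further members of the list were Gbp4 (10.55 ± 0.08), Nos2 (7.51 ± 0.06), the inducible nitric oxide synthase, and Igtp (8.98 ± 0.08), each with an adjusted p of at most 1.59e-22.

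All 29 type I interferon-stimulated genes rose in control cells (median 5.31, or 4.99 at the bounds, adjusted p = 0.00015 with an estimated correlation), such as Oas3 (7.49 ± 0.09), Zbp1 (8.80 ± 0.13) and Irf7 (6.31 ± 0.11). Of 23 genes of MHC class I presentation, 21 rose and 2 fell (median 3.16, adjusted p = 0.00015 with an estimated correlation). The peptide transporter gene Tap1 (7.57 ± 0.07) and the immunoproteasome genes Psmb9 (7.77 ± 0.11) and Psmb8 (5.02 ± 0.07) were among the rises, and the chaperone genes Calr and Pdia3 were the 2 that fell. All 7 genes of MHC class II presentation rose (median 8.61, or 5.85 at the bounds, adjusted p = 0.00285 with an estimated correlation), including Ciita (8.61 ± 0.33), its master regulator, and Cd74 (7.78 ± 0.11), the invariant chain. H2-Ab1, a class II beta chain, rose at least 62-fold to 9.69 ± 0.912 CPM. Of 16 immune checkpoint and NK cell ligand genes, 12 rose and 1 fell, Ulbp1 (adjusted p = 0.00281 with an estimated correlation). Cd274, which encodes PD-L1, rose by 6.45 ± 0.16 and Fas, a death receptor gene, by 3.65 ± 0.12.

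In control cells 21 of 23 JAK-STAT components rose and none fell (median 1.44, adjusted p = 0.00281 with an estimated correlation), among them Stat2 (4.02 ± 0.08) and the feedback inhibitors Socs1 (2.98 ± 0.09) and Socs3 (2.11 ± 0.06). Of 27 NF-kB inflammatory genes, 23 rose and Ptgs2 fell (adjusted p = 0.00281 with an estimated correlation), with the adhesion molecule Icam1 at 8.33 ± 0.14. Of 18 myeloid chemoattractants, 11 rose and Mif fell (adjusted p = 3.72e-05, and 0.0487 with an estimated correlation), with Ccl5 at 4.42 ± 0.10 and Ccl2, a monocyte chemokine, at 3.17 ± 0.09. Of 16 acute phase and C/EBP-regulated genes, 11 rose (12 adjusted over the list alone) and Ptgs2 and Mmp3 fell (adjusted p = 0.00285 with an estimated correlation), with complement C3 at 4.26 ± 0.05 and the siderophore-binding Lcn2 at 4.17 ± 0.07. Of 23 cell death genes, 19 rose and 2 fell (adjusted p = 8.54e-08, and 0.0161 with an estimated correlation), with the inflammatory caspase Casp4 at 5.45 ± 0.17 and the pore-forming Gsdmd at 2.24 ± 0.09.

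Sterol and fatty acid synthesis genes fell in control cells after IFN-gamma in 21 of 25 cases and rose in 3, Scd1, Srebf1 and Srebf2 (median -0.58, adjusted p = 3.76e-07, and 0.0161 with an estimated correlation), with Idi1 at -2.04 ± 0.05 and Lss at -1.49 ± 0.05. Mat2a, which makes S-adenosylmethionine, fell from 307.7 ± 0.0306 to 22.8 ± 0.387 CPM (-3.75 ± 0.05). Trmt61a, a tRNA methyltransferase subunit (-3.49 ± 0.11), Mir17hg, the host transcript of the miR-17-92 cluster (-3.66 ± 0.17), Kbtbd8, a ubiquitin ligase adaptor (-4.83 ± 0.30), Nradd (-4.00 ± 0.53), Mcpt8, a mast cell protease gene (-3.97 ± 0.58), and Hpdl (-3.52 ± 0.46) fell as well, with adjusted p of at most 6.4e-06. Zfp335os, annotated as antisense to another gene and uncertain without strand, was 26.8-fold lower (95% counting interval 8.83 to 133). Of 30 proliferation genes, 15 fell and 10 rose (median -0.13, adjusted p = 0.00706, but 0.0574 with an estimated correlation). Among the proliferation genes, Ccne2 (-3.40 ± 0.09), Rrm2 (-1.66 ± 0.05) and Tyms (-1.66 ± 0.06), which act in S phase, fell. The hypoxia and glycolysis list rose in 16 of 25 cases and fell in 3, Ldha, Eno1 and Ankrd37 (median 0.32, adjusted p = 0.00659, but 0.112 with an estimated correlation), with Hk2 at 1.73 ± 0.06. Oxidative phosphorylation genes fell in 23 of 27 cases and rose in 2 (median -0.44, adjusted p = 0.00267, but 0.343 with an estimated correlation).

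In total, IFN-gamma changed 9581 of 13601 genes in control cells (70.4%), 4947 higher and 4634 lower, of which 1681 and 1465 by at least 2-fold. With a joint knockout group per treatment, whose wider spread enters every comparison, 5815 genes were called. Of 126 genes taken by the naming rule here, 17 lost their call in that fit, and none of the 17 is named above.

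In vehicle, the libraries labelled Cebpd knockout had higher levels of interferon gamma response genes than control. Of the 38 interferon gamma response genes, 28 rose and 2 fell, Socs1 (-1.37 ± 0.12) and Wars (-1.21 ± 0.04). Their median was 1.52, or 1.26 at the bounds (adjusted p = 5.09e-06, and 0.0184 with an estimated correlation). H2-Ab1, without a count in control, stood at 0.72 ± 0.335 CPM with sgRNA1 and 1.88 ± 0.388 CPM with sgRNA2, at least 8.33-fold higher. The complement genes C1s2 and Cfb were at least 5.55-fold and 3.30-fold higher, and Tgtp2 at least 3.57-fold. Ifi47, an interferon-inducible GTPase gene beside Tgtp2 on chromosome 11, rose from 0.0775 ± 0.11 to 5.49 ± 0.082 and 6.71 ± 0.186 CPM, a ratio of 78.2 (95% counting interval 26.6 to 381). Nos2 rose by 2.72 ± 0.07, from 7.16 ± 0.407 CPM to 20.8 ± 0.831 with sgRNA1 and 106 ± 0.817 with sgRNA2, and Irf1, an early transcription factor of the response, by 1.68 ± 0.06. These levels stayed below those after IFN-gamma in control, 1310 ± 7.55 CPM for Nos2.

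Type I interferon-stimulated genes rose in 23 of 29 cases in knockout-labelled vehicle libraries, and Eif2ak2 fell (median 1.48, or 1.35 at the bounds, adjusted p = 3.25e-07, and 0.00774 with an estimated correlation). Ifi27 (1.64 ± 0.06), Oasl2 (1.97 ± 0.10) and the RNA sensor gene Dhx58 (2.26 ± 0.13) were among them. MHC class I presentation genes rose in 20 of 23 cases, and Calr fell (median 0.87, adjusted p = 1.02e-13, and 0.00774 with an estimated correlation), with the nonclassical class I gene H2-T23 at 1.95 ± 0.06 and Psmb8 at 2.20 ± 0.07. Of 7 class II genes, 4 rose, H2-Ab1, Cd74 (3.52 ± 0.18), Rfx5 (0.72 ± 0.08) and H2-DMa (0.85 ± 0.18), but the list did not pass (adjusted p = 0.0831), and with a joint knockout group Rfx5 was no longer called (0.82, adjusted p = 0.0584). Checkpoint and NK cell ligand genes rose in 12 of 16 cases, and Pvr and Cd276 fell (median 1.17, adjusted p = 0.000177, and 0.0188 with an estimated correlation), with Nt5e, the ecto-nucleotidase CD73, at 1.09 ± 0.04 and Fas at 2.66 ± 0.12. Acute phase and C/EBP-regulated genes rose in 12 of 16 cases, and Ptgs2 and Csf3 fell, Csf3 not with a joint knockout group (-0.49, adjusted p = 0.231). The list passed (median 2.26, or 1.82 at the bounds, adjusted p = 4.97e-06, and 0.0118 with an estimated correlation). The iron oxidase ceruloplasmin, Cp, rose by 2.14 ± 0.05, Lcn2 by 2.96 ± 0.07 and C3 by 1.14 ± 0.04.

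Ccn5, Gatm and Ptx3 were also higher in knockout-labelled vehicle libraries. Ccn5, a matricellular protein gene on chromosome 2 (163820861 to 163833146), had no count in control and a mean of 3.56 CPM over the 4 libraries of both guides, at least 22.8-fold higher. It was at 6.03 ± 0.344 CPM with sgRNA2, higher than with sgRNA1 by 2.43 ± 0.33 on the log2 scale (adjusted p = 5.83e-06). Gatm, the initial enzyme of creatine synthesis, rose by a ratio of 77.5 (95% counting interval 13.7 to 3080), and the long pentraxin Ptx3 at least 3.78-fold. Hypoxia and glycolysis genes rose in 20 of 25 cases, and Hk2, Pfkl, Eno1 and Pkm fell (median 0.73, adjusted p = 1.21e-14, and 0.00774 with an estimated correlation). Vegfa, the angiogenic growth factor, rose by 2.21 ± 0.06, the mitophagy receptor Bnip3 by 1.72 ± 0.05 and the mTORC1 inhibitor Ddit4 by 1.60 ± 0.05. Ribosomal protein genes rose in 29 of 30 cases (median 0.42, adjusted p = 1.08e-07, but 0.299 with an estimated correlation), beside the larger share of counts such mRNAs took in these libraries. TGF-beta target genes rose in 11 of 17 cases, and Ski, Tgfb1 and Id3 fell (adjusted p = 0.00891, but 0.216 with an estimated correlation). Cell death genes rose in 12 of 23 cases and fell in 5, Bcl2, Bak1, Tnfrsf10b, Xiap and Ripk1 (adjusted p = 0.0338, but 0.235 with an estimated correlation).

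Of 25 sterol and fatty acid synthesis genes, 24 fell in knockout-labelled vehicle libraries and none rose (median -0.64, adjusted p = 2.9e-18, and 0.0055 with an estimated correlation). Fasn, the fatty acid synthase, fell by 1.77 on the log2 scale, from 797 ± 25.8 CPM to 351 ± 14 with sgRNA1 and 155 ± 4.78 with sgRNA2, and Acly changed by -1.12 ± 0.04. Proliferation genes fell in 21 of 30 cases and rose in 6 (median -0.35, adjusted p = 8.91e-06, and 0.0121 with an estimated correlation), with the replicative helicase genes Mcm3 (-1.16 ± 0.03), Mcm4 (-1.22 ± 0.04) and Mcm2 (-1.02 ± 0.04). Mdn1, an ATPase of 60S ribosome assembly, fell from 109 ± 6.85 to 43.2 ± 1.84 and 15.1 ± 0.458 CPM (-2.09 ± 0.05). Ptprz1, a receptor tyrosine phosphatase gene on chromosome 6 (22875502 to 23052916), fell from 2.03 ± 0.494 to 0.121 ± 0.171 and 0.111 ± 0.0837 CPM (-4.13 ± 0.55). Prl3d2 (-3.65 ± 0.33), of the placental prolactin family, Hsf2bp (-2.68 ± 0.36), the transporter genes Slc16a6 (-2.30 ± 0.14) and Slc30a1 (-2.26 ± 0.14), the second of them a zinc exporter, and the chromatin repressor gene Bend3 (-2.07 ± 0.10) fell too, with adjusted p of at most 3.3e-06. Il17d fell by 2.03 ± 0.27 on the log2 scale, but with a joint knockout group it was at -1.60 (adjusted p = 0.0545). Immediate early and MAPK feedback genes fell in 13 of 24 cases and rose in 4, Fos, Junb, Dusp1 and Atf3 (median -0.36, adjusted p = 0.0122, but 0.227 with an estimated correlation).

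The knockout comparison in vehicle called 9207 genes (67.7%), 4621 higher and 4586 lower, of which 1443 and 446 by at least 2-fold, and 4387 with a joint knockout group per treatment, where 29 of 130 genes of the naming rule lost their call. Upper quartile scaling moved the median of all genes by 0.135 and the higher share of calls from 50.2% to 62.1%, so the direction of changes no larger than that depended on the scaling.

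The guides moved genes to different extents in vehicle. With sgRNA1, 7141 genes were called (3487 higher, 3654 lower), and with sgRNA2, 9971 (5212 higher, 4759 lower). Upper quartile scaling moved the higher shares from 48.8% to 62.8% and from 52.3% to 62.5%. A direct test between the guides called 8476 genes. The interferon gamma response list had a median of 0.94 with sgRNA1 (22 rose, 4 fell, adjusted p = 0.0471 with an estimated correlation) and 2.14 with sgRNA2 (30 rose, 2 fell, adjusted p = 0.0265). Sterol synthesis genes had medians of -0.42 and -0.93, with 22 and 24 of 25 falling. Hypoxia and glycolysis genes had medians of 0.18 (14 rose, 7 fell, adjusted p = 0.183 with an estimated correlation) and 1.27 (21 rose, 1 fell, adjusted p = 0.00391). Proliferation genes had medians of -0.13 (adjusted p = 0.163 with an estimated correlation) and -0.45 (adjusted p = 0.0104). Of 6149 genes called with both guides, 5623 (91.4%) had the same sign, 2785 higher and 2838 lower, where independent lists would share 1336 and 1279. The fold changes correlated across genes at r = 0.749, against 0.495 in 20 simulations of unchanged groups with the same controls, and their covariance was 0.676 against 0.0685. Part of the excess may come from the shared controls, which were not split since each part would hold 1 library, and genes are not independent replicates.

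**Figure D2:**
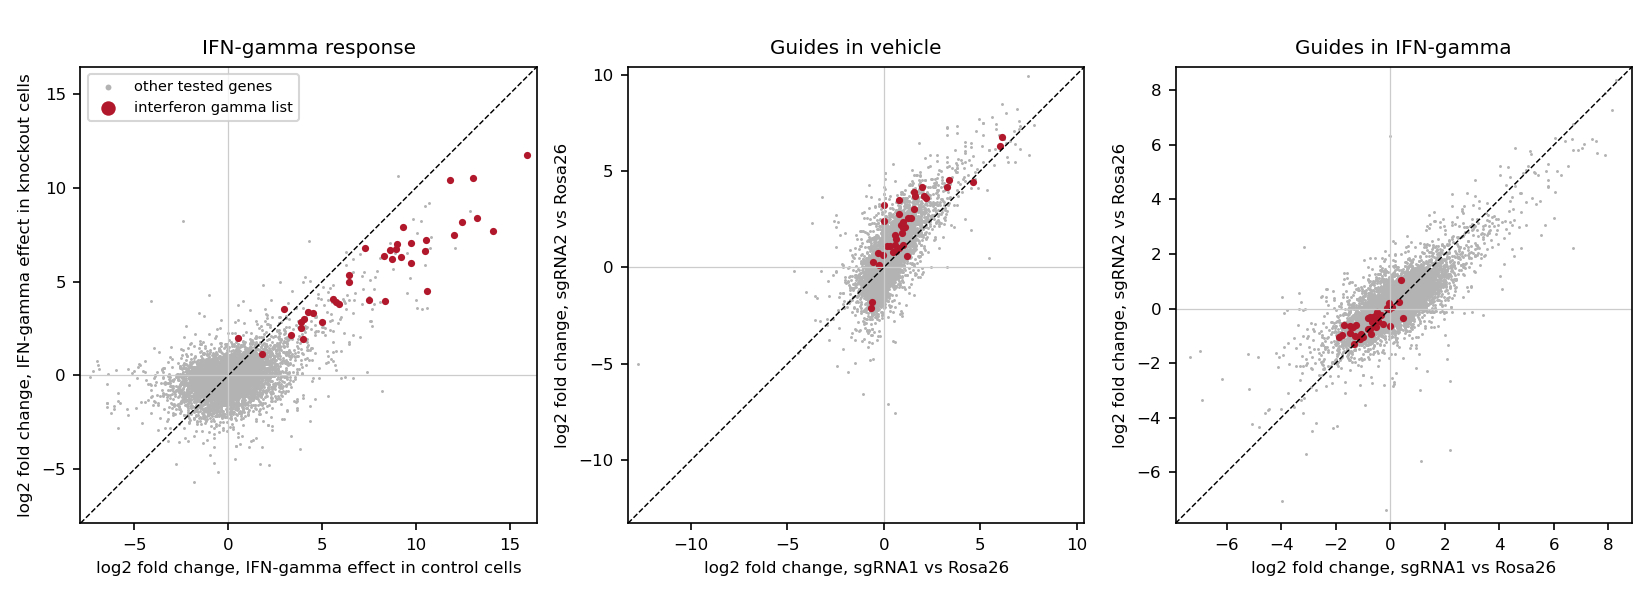
Log2 fold changes of all tested genes in 3 pairs of comparisons, with each point a gene and interferon gamma response genes in red. The panels set the response to IFN-gamma in control against that in knockout-labelled cells (x and y axes), and sgRNA1 against sgRNA2 in vehicle and in IFN-gamma. In the vehicle panel the fold changes correlate at r = 0.749.

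After IFN-gamma, the knockout-labelled libraries had lower levels of many interferon gamma response genes than control, the opposite of vehicle. Of 38 such genes, 31 were lower and 2 higher, Cxcl11 (0.71) and Wars (0.28), with a median of -0.56 (adjusted p = 1.06e-13, and 0.0219 with an estimated correlation). The GTPase genes Gbp4 (-1.01 ± 0.03) and Gbp10 (-1.38 ± 0.05) and the ubiquitin ligase gene Dtx3l (-1.15 ± 0.05) were among those lower. JAK-STAT components were lower in 18 of 23 cases and higher in 2, Socs2 and Ptpn2 (3 adjusted over the list alone), with a median of -0.58 (adjusted p = 1.53e-05, but 0.0582 with an estimated correlation). Jak2 was at -0.97 ± 0.04, Stat3 at -0.81 ± 0.05 and Tyk2 at -1.16 ± 0.07. MHC class I genes were lower in 14 of 23 cases and higher in 3, Tapbpl, Psme2 and Calr (median -0.17, adjusted p = 0.0395, but 0.332 with an estimated correlation). The class I call was lost with upper quartile scaling (adjusted p = 0.111), library totals (0.15), and without control IFN-gamma replicate 1 (0.0538) or sgRNA1 IFN-gamma replicate 2 (0.0615), and by guide the medians were -0.36 (adjusted p = 0.00753) and -0.03 (adjusted p = 0.285).

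Il6 and Ccl2 were higher in knockout-labelled libraries after IFN-gamma, but the inflammatory lists went both ways. The cytokine Il6 rose from 0.93 ± 0.357 CPM in control to 20.7 ± 0.911 with sgRNA1 and 15.8 ± 1.74 with sgRNA2 (4.29 ± 0.21, adjusted p = 5.95e-12). Ccl2 rose from 35.8 ± 0.281 to 257 ± 4.47 and 199 ± 8.75 CPM (2.66 ± 0.05). Myeloid chemoattractants were higher in 12 of 18 cases and lower in 3, Cx3cl1 (-1.66 ± 0.04), Csf1 and Mif (median 0.60, or 0.59 at the bounds, adjusted p = 0.000735, but 0.137 with an estimated correlation). NF-kB inflammatory genes were higher in 8 of 27 cases and lower in 10 (median -0.03, mean 0.22, adjusted p = 0.474, but 0.0473 with sgRNA1 alone), with the inhibitor Nfkbia at -0.63 ± 0.04. Acute phase and C/EBP-regulated genes were higher in 8 of 16 cases and lower in 5, Lcn2, C3, Socs3, Mmp3 and Cdkn2c (median 0.16, adjusted p = 0.229). Cyp1b1, a cytochrome P450 of steroids and xenobiotics (chromosome 17, 79701537 to 79715061), rose from 11.1 ± 0.69 to 169 ± 5.27 and 107 ± 1.04 CPM (3.60 ± 0.07). The neuropeptide gene Nts (5.15 ± 0.38), Ptx3 (5.12 ± 0.51) and the receptor gene Fgfr1 (3.47 ± 0.44) rose with adjusted p of at most 1.61e-06. Gatm was at least 13.4-fold higher, and ratios were 47.4 for the protease inhibitor Serpinb2 (95% counting interval 12.9 to 394) and 29.2 for the activin subunit Inhbb (9.85 to 143). Stress response genes of the integrated stress and unfolded protein list were higher in 15 of 22 cases and lower in 4, Hspa5, Xbp1, Dnajc3 and Hsp90b1, which encode or drive chaperones of the endoplasmic reticulum (median 0.63, adjusted p = 6.96e-06, but 0.0582 with an estimated correlation). Atf4, its central transcription factor, rose by 1.07 ± 0.04, Atf3 by 1.15 ± 0.05 and Chac1 by 1.61 ± 0.07. Antioxidant genes were higher in 13 of 20 cases and lower in 5, Gstm1, Gstp1, G6pdx, Sod1 and Cat (median 0.22, adjusted p = 0.0204, but 0.315 with an estimated correlation and 0.124 with sgRNA1 alone), with Hmox1 at 1.29 ± 0.06.

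Asb2, Aqp1 and Dmpk were among the genes lower in knockout-labelled libraries after IFN-gamma. Asb2, a ubiquitin ligase subunit (chromosome 12, 103321142 to 103356001), was at 22.3 ± 1.29 CPM in control and 0.648 ± 0.144 and 1.14 ± 0.326 CPM with the guides (-4.66 ± 0.19). The water channel Aqp1 fell from 25.5 ± 0.0948 to 1.58 ± 0.343 and 2.06 ± 0.806 CPM (-3.84 ± 0.15), and the kinase gene Dmpk from 29.3 ± 0.459 to 3.27 ± 0.614 and 2.97 ± 0.405 CPM (-3.22 ± 0.11). Ptprz1 (-4.57 ± 0.45), the adducin Add2 (-4.05 ± 0.42), Sectm1a (-3.44 ± 0.24) and the immunoglobulin transporter Pigr (-3.42 ± 0.30) were lower with adjusted p of at most 1.11e-07, and Dmp1 was 20.6-fold lower (95% counting interval 6.39 to 106). Epithelial genes were lower in 15 of 23 cases and higher in 7 (median -0.28, adjusted p = 0.0154, but 0.188 with an estimated correlation), with Ehf at -1.39 ± 0.05 and Epcam at -0.93 ± 0.04. Mesenchymal genes were lower in 8 of 13 cases and higher for Loxl2 alone (3.17), with a median of -0.68 (adjusted p = 0.00568, but 0.137 with an estimated correlation), Sparc at -0.91 ± 0.04 and Vim at -0.78 ± 0.04. Sterol synthesis genes were lower in 18 of 25 cases and higher in 4, Idi1, Lss, Cyp51 and Sc5d (median -0.32, adjusted p = 0.000633, but 0.131 with an estimated correlation), with Acaca at -0.94 ± 0.04. Mitochondrially encoded genes were lower in 11 of 13 cases (median -1.01, adjusted p = 0.000735, but 0.487 with an estimated correlation), beside the lower shares of counts given above. Oxidative phosphorylation genes were higher in 17 of 27 cases (18 adjusted over the list alone) and lower in 3 (4 over the list alone; median 0.25). Their call (adjusted p = 0.0365) was lost with an estimated correlation (0.524), with sgRNA1 alone (0.319) and without control IFN-gamma replicate 2 (0.0513).

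The knockout comparison in IFN-gamma called 8959 genes (65.9%), 4418 higher and 4541 lower, of which 900 and 551 by at least 2-fold, and 4361 with a joint knockout group, where 28 of 127 genes of the naming rule lost their call. Scaling by library totals moved the median of all genes by 0.125 and the higher share of calls from 49.3% to 60.4%. The guides alone called 8825 and 8402 genes, with higher shares moved by scaling from 48.7% to 63.3% for sgRNA1 (library totals) and from 48.9% to 58.2% for sgRNA2 (upper quartile). Of 6733 genes called with both guides, 6269 (93.1%) had the same sign, 2913 higher and 3356 lower, where independent lists would share 1298 and 1429. Fold changes correlated at r = 0.787, against 0.515 in simulations with the same controls, with a covariance of 0.575 against 0.0684, and part of that may come from the controls. A direct test between the guides called 6518 genes, and library totals moved its higher share from 48.8% to 33.0%.

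The knockout differences in vehicle and in IFN-gamma rest on separate libraries of the same cell lines. Of 6714 genes called in both, 3768 (56.1%) had the same sign and 2946 opposite signs, 1387 of these higher in vehicle and lower in IFN-gamma and 1559 the reverse. In total, opposite signs were no more frequent than independent lists would give. Shared rises numbered 1691, where independent lists would give 1501, and shared falls 2077, against 1531, and the fold changes correlated across genes at r = 0.158.

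In knockout-labelled cells, IFN-gamma also raised interferon-induced genes. All 38 interferon gamma response genes rose (median 5.67, adjusted p = 0.000204 with an estimated correlation), as did all 29 type I interferon-stimulated genes (median 3.47, adjusted p = 0.0007) and all 7 class II genes (median 3.81, adjusted p = 0.00319). Cxcl9 rose from 0.0553 ± 0.00708 to 284 ± 7.02 CPM with sgRNA1 and from 0.109 ± 0.00691 to 299.9 ± 6.61 CPM with sgRNA2 (11.77 ± 0.09). Iigp1 (10.42 ± 0.10), Apol6 (8.74 ± 0.17), Tgtp1 (8.41 ± 0.12) and Mpeg1, which encodes the pore-forming perforin-2 (9.20 ± 0.20), rose with adjusted p of at most 2.16e-17. Ratios were 1550 for Batf2 (95% counting interval 278 to 61200), 1130 for the serpin Serpina3f (313 to 9340) and 553 for the class II alpha chain H2-Aa (98.9 to 21900). Gbp4 rose by 7.23 ± 0.05 and Oasl2 by 3.85 ± 0.04. MHC class I genes rose in 21 of 23 cases, and Calr and Pdia3 fell (median 2.12, adjusted p = 0.000658 with an estimated correlation).

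NF-kB inflammatory genes rose in knockout-labelled cells with IFN-gamma in 25 of 27 cases (median 1.07, adjusted p = 0.000658 with an estimated correlation), with Icam1 at 3.99 ± 0.06 and Ptgs2, the inducible cyclooxygenase, at 1.40 ± 0.03. Myeloid chemoattractants rose in 14 of 18 cases, and Ccl9 and Mif fell (median 1.57, adjusted p = 0.00319 with an estimated correlation), with Ccl2 at 3.87 ± 0.05 and the neutrophil growth factor Csf3 at 1.80 ± 0.03. Acute phase and C/EBP-regulated genes rose in 11 of 16 cases and fell in 4, Cp, Fabp4, Mmp3 and Cdkn2c (median 1.22, adjusted p = 0.00319 with an estimated correlation). JAK-STAT components rose in 14 of 23 cases and fell in 3, Ifngr1, Ifnar1 and Il6ra (adjusted p = 0.00733 with an estimated correlation), and checkpoint and NK cell ligand genes rose in 10 of 16 and fell in 4, Vtcn1, Raet1e, Ulbp1 and H60b (adjusted p = 0.0111). Stress response genes rose in 16 of 22 cases and fell in 4, Hspa5, Xbp1, Dnajb9 and Hsp90b1 (median 0.81, adjusted p = 0.00486 with an estimated correlation), with Atf3 at 2.91 ± 0.04, Chac1 at 2.80 ± 0.06 and the asparagine synthetase Asns at 1.48 ± 0.04. Cell death genes rose in 16 of 23 cases and fell in 5, among them Mcl1 and Xiap (adjusted p = 4.27e-06, but 0.0506 with an estimated correlation).

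Of 25 hypoxia and glycolysis genes, 19 fell in knockout-labelled cells with IFN-gamma and 5 rose, Hk2, Pfkfb3, Pfkp, Pfkl and Ndrg1 (median -0.35, adjusted p = 6.29e-07, and 0.0306 with an estimated correlation). The list median was 0.15 with sgRNA1 alone, where the test turned to a rise (adjusted p = 0.467), and -0.94 with sgRNA2. Ankrd37, a target of hypoxia-inducible factors, fell from 20.7 ± 1.82 to 6.26 ± 1.75 CPM with sgRNA1 and from 99.6 ± 2.47 to 4.42 ± 0.427 CPM with sgRNA2 (-3.11 ± 0.09), and Adm, a vasodilator peptide gene, by 2.28 ± 0.08 on the log2 scale. All 30 ribosomal protein genes fell (median -0.59, adjusted p = 2.21e-11, but 0.209 with an estimated correlation), as did 12 of 13 mitochondrially encoded genes (13 adjusted over the list alone; median -0.91, adjusted p = 6.83e-05, but 0.285 with an estimated correlation), along with the shares of counts these mRNAs took. Oxidative phosphorylation genes fell in 19 of 27 cases and rose in 3 (adjusted p = 0.000578, but 0.256 with an estimated correlation and 0.211 with sgRNA2 alone). Dmp1, a bone matrix protein gene, was 57.2-fold lower (95% counting interval 19.2 to 280). Add2 (-4.44 ± 0.37), the keratin Krt13 (-3.51 ± 0.32), the receptor component Ramp1 (-3.25 ± 0.16), Rdm1 (-3.06 ± 0.12), Fam227a (-2.82 ± 0.32) and Zfp773 (-2.45 ± 0.21) fell with adjusted p of at most 3.24e-07. Sterol synthesis genes fell in 13 of 25 cases and rose in 6 (median -0.21, adjusted p = 0.00526, but 0.129 with an estimated correlation and 0.557 with sgRNA2 alone).

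IFN-gamma changed 9372 genes (68.9%) in knockout-labelled cells, 4717 higher and 4655 lower, of which 692 and 869 by at least 2-fold (478 lower with a filter at 1 CPM on average), and 4915 with a joint knockout group, where 9 of 129 genes of the naming rule lost their call. Upper quartile scaling moved the median of all genes by -0.108 and the higher share from 50.3% to 39.4%, and library totals moved them by 0.109 and to 61.5%. Of 7132 genes called in both cell types, 4848 (68%) moved the same way and 2284 the opposite way. Shared rises numbered 2698 (1716 for independent lists) and shared falls 2150 (1586), with r = 0.543 across genes. By guide, 5867 genes were called with both, 4981 (84.9%) with the same sign, at r = 0.697.

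**Figure D3:**
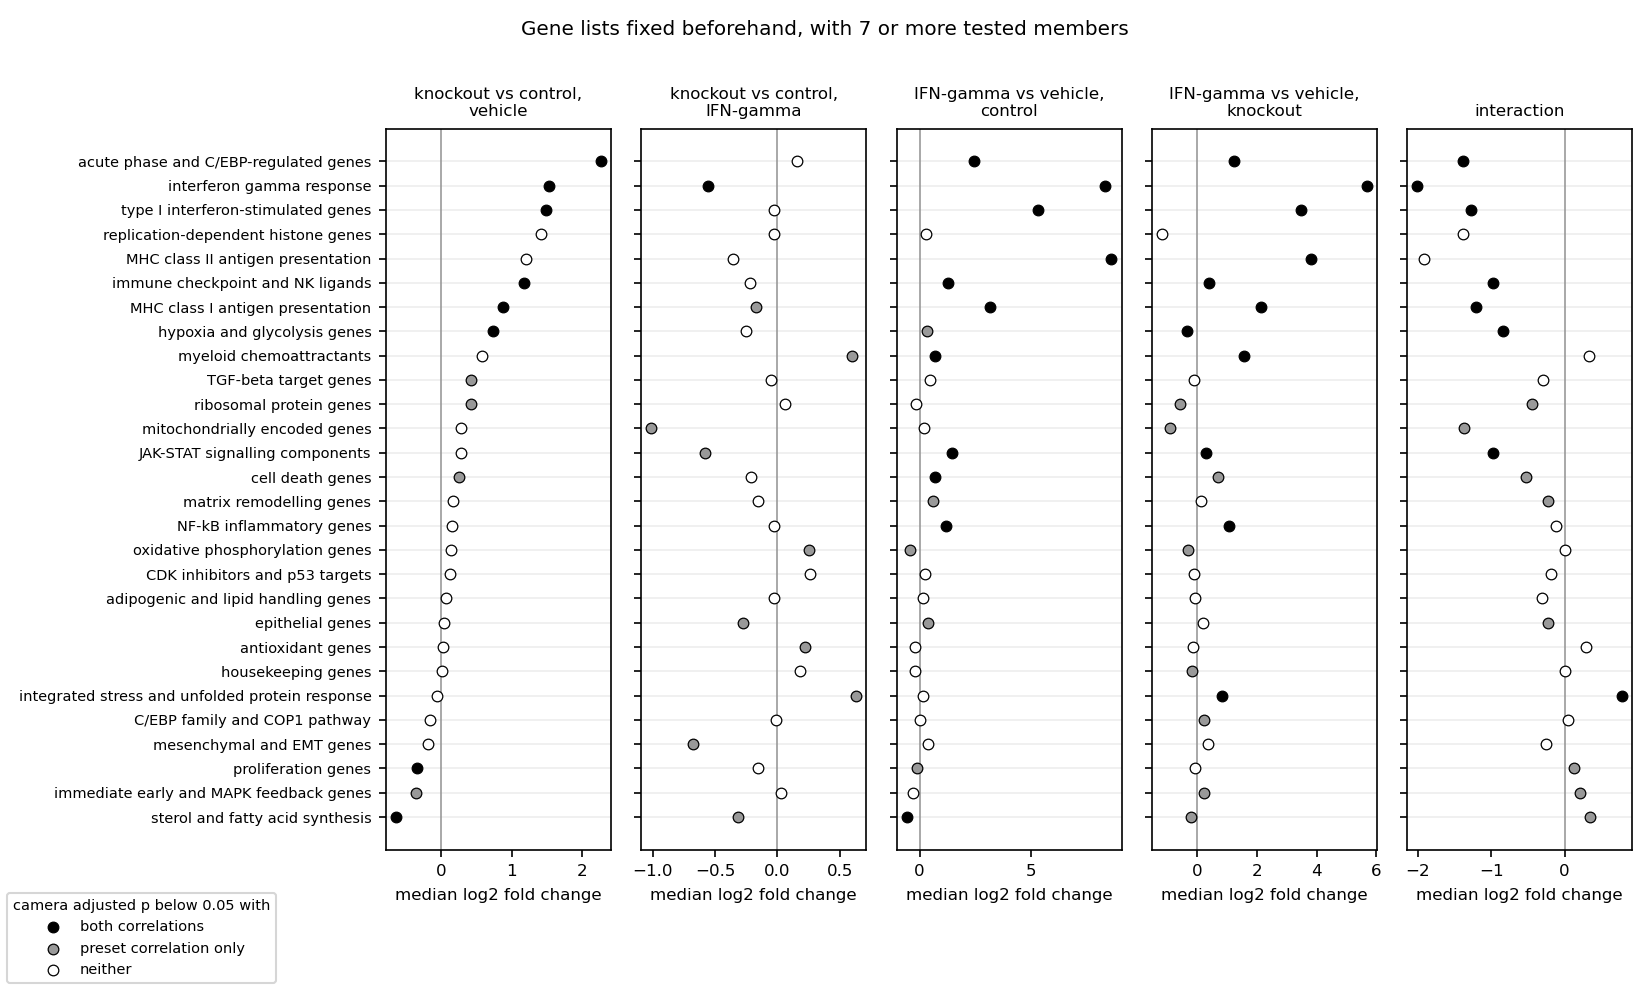
Median log2 fold change of each gene list with at least 7 tested members in the 5 comparisons, with filled black points for lists called with preset and estimated correlation, grey with the preset alone and white with neither. The interferon gamma response list lies at 1.52 in vehicle and -0.56 in IFN-gamma for the knockout comparison.

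The interaction tests whether the response to IFN-gamma differed between knockout-labelled and control cells, and 3 of the 4 lists of interferon-induced and antigen presentation genes were lower in it. A lower value there can come from higher vehicle levels as well as from lower levels after IFN-gamma. Of 38 interferon gamma response genes, 30 were lower (32 adjusted over the list alone) and 2 higher, Socs1 (0.56) and Wars (1.49), with a median of -2.01 (adjusted p = 8.75e-09, and 0.0158 with an estimated correlation). Nos2 was at -3.49 ± 0.08, Irf1 at -2.15 ± 0.07 and Gbp4 at -3.32 ± 0.14. Type I interferon-stimulated genes were lower in 25 of 29 cases, and Eif2ak2 was higher (median -1.28, adjusted p = 1.4e-05, and 0.0158 with an estimated correlation), with Ifi27 at -1.89 ± 0.07 and Oas3 at -3.32 ± 0.17. MHC class I genes were lower in 20 of 23 cases, and Calr was higher (median -1.21, adjusted p = 6.87e-14, and 0.0158 with an estimated correlation), with H2-T23 at -2.70 ± 0.07. Of 7 class II genes 4 were lower, but the list did not pass (median -1.92, adjusted p = 0.0789) except with fry (1.62e-06), library totals (0.0396) and sgRNA2 alone (0.0475), and Rfx5 was among the 4 but lost with a joint knockout group (-1.18, adjusted p = 0.0611). For H2-T23 the vehicle levels were 19.4 ± 0.351, 34.6 ± 0.861 and 163 ± 7.54 CPM in control, sgRNA1 and sgRNA2, and the IFN-gamma levels 630 ± 8.95, 274 ± 3.18 and 513 ± 24.7 CPM. Ifi47 was at -6.10 ± 0.33, from higher vehicle levels and 129.7 ± 1.96, 124 ± 7.75 and 150.2 ± 0.109 CPM after IFN-gamma. H2-Ab1, C1s2, Cfb and Tgtp2 were also lower in the interaction, with adjusted p of at most 3.27e-05. As they had no count in control vehicle libraries, their fitted size depends on the prior count. Serpinb8 was at -5.19 ± 0.79. Ccn5 and Oas2 were called (adjusted p = 0.0114 and 0.0179) but lost with a joint knockout group (0.144 and 0.0621). Ccn5 was also lost without control IFN-gamma replicate 2 (log2 value -4.94). Oas2 was lost without control vehicle replicate 1 or 2 (-5.14 each) or sgRNA1 vehicle replicate 2 (-3.24).

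Acute phase and C/EBP-regulated genes were lower in the interaction in 9 of 16 cases and higher for Ptgs2 (1.88 ± 0.06) and Csf3 (0.88 ± 0.06, but 0.79 with adjusted p = 0.193 for a joint knockout group). The list passed (median -1.38, adjusted p = 0.00123, and 0.041 with an estimated correlation), with Lcn2 at -3.22 ± 0.08, C3 at -2.63 ± 0.06 and Cp at -2.10 ± 0.06. In the knockout comparisons above, this list was higher in vehicle and was not called in IFN-gamma. JAK-STAT components were lower in 19 of 23 cases and higher in 3, Stat6, Socs1 and Ptpn2 (median -0.97, adjusted p = 1.32e-05, and 0.0246 with an estimated correlation), with Jak2 at -1.22 ± 0.06. Checkpoint and NK cell ligand genes were lower in 11 of 16 cases and higher for Pvr (median -0.98, adjusted p = 0.000191, and 0.0246 with an estimated correlation). Hypoxia and glycolysis genes were lower in 21 of 25 cases and higher for Ldha and Eno1 (median -0.84, adjusted p = 1.58e-12, and 0.0158 with an estimated correlation), with the carbonic anhydrase Car9 at -2.31 ± 0.06 and Ddit4 at -2.27 ± 0.07. The guides differed here, as the median response of this list to IFN-gamma was 0.32 in control, 0.15 with sgRNA1 and -0.94 with sgRNA2. Cell death genes were lower in 15 of 23 cases and higher in 4, Bak1, Tnfrsf10b, Ripk1 and Mlkl (adjusted p = 0.00695, but 0.148 with an estimated correlation). Matrix remodelling genes were lower in 15 of 25 cases (adjusted p = 0.00937, but 0.0949 with an estimated correlation and 0.109 with sgRNA1 alone), with Mmp9, a gelatinase, at -2.39 ± 0.05, and epithelial genes in 11 of 23 (adjusted p = 0.00937, but 0.115 with an estimated correlation and 0.097 with sgRNA1 alone).

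Stress response genes had higher values in the interaction, with members of the list on both sides. They were higher in 13 of 22 cases and lower in 7 (8 adjusted over the list alone), with a median of 0.78 (adjusted p = 5.31e-05, and 0.0414 with an estimated correlation). The serine and folate pathway genes Shmt2 (1.97 ± 0.06) and Mthfd2 (2.16 ± 0.08) and the transcription factor Atf4 (1.52 ± 0.05) were among them. Rrp12, a ribosomal RNA processing factor, was at 3.45 ± 0.09, falling from 60.5 ± 1.89 to 10.6 ± 0.175 CPM in control against 36 ± 0.634 to 40.5 ± 1.72 with sgRNA1 and 6.24 ± 0.167 to 20.3 ± 0.735 with sgRNA2. Kbtbd8 (5.27 ± 0.37), Prl3d2 (4.58 ± 0.51), Serpinb2 (4.04 ± 0.81), Slc16a6 (3.70 ± 0.21) and the trichohyalin gene Tchh (3.63 ± 0.65) were higher with adjusted p of at most 0.000274. Trmt61a (3.70 ± 0.14) and the immediate early gene Egr1 (3.47 ± 0.26) were too, but not with a joint knockout group (3.23, adjusted p = 0.0612, and 3.89, adjusted p = 0.0873). Sterol synthesis genes were higher in 18 of 25 cases and lower in 3, Insig1, Scd1 and Srebf2 (median 0.34, adjusted p = 0.000958, but 0.0773 with an estimated correlation and 0.0767 with sgRNA1 alone). Immediate early genes were higher in 12 of 24 cases and lower in 3, Fosl2, Junb and Dusp4 (adjusted p = 0.00426, but 0.171 with an estimated correlation and 0.206 with sgRNA2 alone). Proliferation genes were higher in 15 of 30 cases and lower in 13 (median 0.13, adjusted p = 0.00937, but 0.0619 with an estimated correlation and 0.119 with sgRNA1 alone), with Ccne2 at 3.02 ± 0.11 and Tyms at 1.83 ± 0.07. Ribosomal protein genes were lower in 25 of 30 cases (26 adjusted over the list alone; adjusted p = 0.000958, but 0.515 with an estimated correlation and 0.179 with sgRNA2 alone) and mitochondrially encoded genes in 11 of 13 (adjusted p = 0.000343, but 0.366 with an estimated correlation), beside the shares of counts given above.

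The interaction was called for 8688 genes (63.9%), 4152 higher and 4536 lower, of which 1274 and 1648 by at least 2-fold, and for 2663 with a joint knockout group, where 46 of 130 genes of the naming rule lost their call. Library totals moved the median of all genes by 0.148 and the higher share from 47.8% to 57.8%.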

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

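The interaction test and the test of GC content and transcript length were fixed before their results were seen, and the other tests in this part were chosen only after.

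A difference between control and knockout-labelled cells in the response to IFN-gamma was called for 8688 genes by the interaction test, and the values in this paragraph are listed because they passed that test of a difference between cell types. Larger interaction values were 5.27 for Kbtbd8, 4.58 for Prl3d2, 4.04 for Serpinb2, 3.70 for Slc16a6, 3.70 for Trmt61a, 3.63 for Tchh, 3.47 for Egr1 and 3.45 for Rrp12. Lower values were -6.99 for H2-Ab1, -6.81 for C1s2, -6.46 for Cfb, -6.39 for Tgtp2, -6.10 for Ifi47, -5.51 for Ccn5, -5.19 for Serpinb8 and -5.14 for Oas2. For H2-Ab1, C1s2, Cfb, Tgtp2 and Ifi47 the knockout differences in vehicle were 7.55, 7.1, 6.37, 6.45 and 6.17. Their interaction values thus came mostly from higher vehicle levels, not from lower levels after IFN-gamma. Of the genes listed, H2-Ab1, C1s2, Cfb, Tgtp2, Ccn5 and Oas2 had no count in control vehicle libraries, so their values depend on the prior count. Ifi47 had 3 counts there and Serpinb2 had 2 in control IFN-gamma libraries, so their values rest on few counts. With a joint knockout group per treatment Ccn5, Oas2, Trmt61a and Egr1 were no longer called (adjusted p = 0.144, 0.0621, 0.0612 and 0.0873). Without sgRNA1 vehicle replicate 2, Oas2 was at -3.24. List medians were -2.01 for the interferon gamma response, -1.28 for type I interferon-stimulated genes, -1.21 for MHC class I presentation, -1.38 for acute phase and C/EBP-regulated genes, -0.97 for JAK-STAT components, -0.98 for checkpoint and NK cell ligands, -0.84 for hypoxia and glycolysis, and 0.78 for the stress response list. Negative list medians can also come from higher vehicle levels. In vehicle the interferon gamma, class I and acute phase lists were higher in knockout-labelled libraries, by medians larger in size than those in IFN-gamma. The acute phase list was not called in IFN-gamma, whereas JAK-STAT components were lower there with the preset correlation. For hypoxia and glycolysis genes, the median response to IFN-gamma was 0.32 in control, 0.15 with sgRNA1 and -0.94 with sgRNA2.

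Interferon-induced genes such as Nos2, Irf1, Ifi47 and H2-T23 were higher in the vehicle libraries of both guides. Reads leaked from the IFN-gamma libraries would leave each abundant member at about 1 share of its IFN-gamma level, but over 37 members the share ran from 0% (Batf2) to 42.7% with sgRNA1 and from 0.0362% (Cxcl9) to 48.6% with sgRNA2. The lowest share was at most 0.0133 of the median share, which argues against leakage as the whole cause. Interferon in the vehicle cultures of the knockout-labelled cells and a higher baseline through loss of Cebpd both stay open, as no value given here excludes either. With a single control line, a low baseline in that line also remains open and was not tested.

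Outside the interferon lists, the difference between sgRNA2 and sgRNA1 in vehicle followed the response of control cells to IFN-gamma, although they share no library (r = 0.650, Spearman 0.731, across 11818 genes, which are not independent replicates). With the trend in GC content and transcript length removed over the 11627 genes that had both, the correlation was 0.653, which argues against such a bias as the whole cause. For IFN-gamma signalling in the sgRNA2 vehicle cultures, a slope at least as steep was predicted for the interferon gamma response list. The slope of its 38 genes was 0.239 of the slope outside, 0.101 (SE 0.0409) against 0.424 (SE 0.00455). Each slope had its own intercept and so leaves out a shift of the whole list, whose median guide difference was 0.99. The slopes therefore cannot decide whether such signalling was a cause. A growth or culture state that differed between cultures may be a cause, but stays open: 2 of 3 growth lists had the same sign in both differences (proliferation -0.20 and -0.13, sterol synthesis -0.63 and -0.58, ribosomal proteins 0.22 and -0.15), and the sources used here give no culture density. A difference in what the guides did to Cebpd or elsewhere in the genome is an untested biological explanation.

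With both guides in both treatments, 142 genes were at least 2-fold higher than control and 11 at least 2-fold lower. The ratio of higher to lower genes was 12.9, and 10.7, 17.4 and 16.1 with DESeq2's size factors, upper quartile scaling and library totals. The choice among these scalings was thus not the whole cause. They moved the median of all genes by at most 0.175 (sgRNA1 in IFN-gamma, library totals), less than the 2-fold limit. A larger scaling error was not tested. Loss of expression in the single control line and a rise through loss of Cebpd cannot be told apart, since both predict genes near 0 in all 4 control libraries and present in all 8 others. With limits of at most 3 counts in each control library and at least 0.5 CPM in each other library, there were 3 such genes, Cbr3, Ccn5 and Gatm, named after their values were seen, and 0 of the opposite kind.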

How the results depend on the processing

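All alternatives in this part were fixed before the data were examined, and no test was chosen after. The numbers of called genes were lowest when both guides were put into a joint knockout group per treatment, which adds the difference between the guides to the spread. That fit still counts the 4 knockout-labelled libraries of each treatment as separate replicates. They come from 2 cell lines, and the single control line gives no spread between control lines. With the joint group, knockout in vehicle called 4387 genes (9207 before), knockout in IFN-gamma 4361 (8959), IFN-gamma in control 5815 (9581), IFN-gamma in knockout 4915 (9372) and the interaction 2663 (8688). The genes still called had the same sign as before in 4387, 4360, 5814, 4915 and 2663 cases. Over all other alternatives except left-out libraries, the counts ran from 8493 to 9273, 8221 to 9033, 8918 to 9681, 8606 to 9477 and 7975 to 8692 in that order. Leaving out 1 library at a time gave 8144 to 9297, 7799 to 8999, 8753 to 9677, 8819 to 9382 and 8031 to 8631, with the lone library of a group assumed to vary like the others. The fit to only the groups named gives no value for the interaction.

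Lists called fell with an estimated correlation, as that setting widens the null for correlated members. They went from 13 to 8 for knockout in vehicle and from 11 to 1 for knockout in IFN-gamma. For IFN-gamma in control they went from 16 to 11, for IFN-gamma in knockout from 19 to 11 and for the interaction from 16 to 8. With fry, which tests each list on its own and not against other genes, more lists were called. The numbers were 29 for knockout in vehicle, 25 for knockout in IFN-gamma, 29 for IFN-gamma in control (16 with camera), 28 for IFN-gamma in knockout and 29 for the interaction. Directions turned in 3 cases, and the cause was not tested. With sgRNA1 alone, ribosomal protein genes were lower in IFN-gamma (adjusted p = 0.0473; 3.97e-05 with sgRNA2, which was higher) and hypoxia and glycolysis genes had a rising direction with IFN-gamma (adjusted p = 0.467). With fry, mesenchymal genes rose with IFN-gamma in knockout-labelled cells (adjusted p = 0.0437), where their median was 0.34, their mean -0.01 and camera's direction down. Counts of genes at least 2-fold lower also moved. With upper quartile factors they went from 446 to 276 for knockout in vehicle and from 146 to 96 for sgRNA1 in vehicle, and with library totals from 551 to 365 for knockout in IFN-gamma and from 771 to 495 for sgRNA1 in IFN-gamma. A filter at 1 CPM on average, which tests fewer genes, took them from 869 to 478 for IFN-gamma in knockout, and from 11 to 6 for both guides in both treatments. A joint knockout group took them from 446 to 220 for knockout in vehicle and from 1648 to 953 for the interaction, where those at least 2-fold higher went from 1274 to 601. Genes with the same sign in both knockout comparisons went from 3768 to 1422 and in both IFN-gamma comparisons from 4848 to 2337 with that group.

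The replicate numbers did not pair the samples. Over 15 pairs of groups, deviations of same-numbered libraries correlated at -0.14 to 0.0552 across 11945 genes, with 0 pairs over 0.1. With the replicate block the 5 comparisons called 9191, 8911, 9539, 9317 and 8644 genes, and of all list calls it ended that of fibroblast markers in vehicle (adjusted p = 0.0544).

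At this depth, bounds for genes without counts in control vehicle libraries rest on a floor of 3 counts per library, and folds above those bounds were not measurable.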

Other observations

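The test over other splits of the libraries was fixed before its result was seen, and the genes named in the next paragraph were chosen after their values were seen.

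Several genes were at least 2-fold apart from control with both guides in both treatments. Wnt11, a Wnt ligand, had no count in the 4 control libraries and stood at 0.498 ± 0.0637 and 1.59 ± 0.244 CPM in vehicle and 1.49 ± 0.143 and 1.51 ± 0.14 CPM in IFN-gamma with sgRNA1 and sgRNA2. Il13ra2, a decoy receptor for interleukin 13, was at 0.0517 ± 0.073 CPM in control and 1.70 ± 0.333 and 1.02 ± 0.395 CPM with the guides in vehicle. Cyp1b1 was at 5.77 ± 1.19 CPM in control and 96.8 ± 0.778 and 88.4 ± 6.37 CPM in vehicle. On the lower side, Gpnmb, a transmembrane glycoprotein gene, was at 36.5 ± 2.52 CPM in control, 10.7 ± 0.0706 with sgRNA1 and 11.1 ± 0.67 with sgRNA2 in vehicle, and at 55.5 ± 1.31, 9.77 ± 0.168 and 10.2 ± 1.39 CPM in IFN-gamma. The adhesion gene Sele fell from 2.08 ± 0.272 to 0.357 ± 0.42 and 0.0567 ± 0.0802 CPM in vehicle, and Gas1, a growth arrest gene, from 2.68 ± 0.286 to 0.533 ± 0.185 and 0.297 ± 0.0194 CPM.

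Members of the C/EBP family and the COP1 pathway that degrades C/EBP proteins went both ways. In vehicle, 4 of 17 were higher with the guides (Cebpb, Cebpd, Ddit3 and Rbx1) and 9 lower (median -0.16, adjusted p = 0.321), with the calls of Ddit3, Cebpd, Cebpz and Atf4 lost for a joint knockout group (adjusted p = 0.0652, 0.133, 0.0723 and 0.158). With IFN-gamma in control 5 rose, Cebpd by 2.66 ± 0.10, Ddit3 by 2.38 ± 0.08 and Cebpb by 1.28 ± 0.07 beside Trib3 and Cop1, and 8 fell, and in knockout-labelled cells 10 rose and 3 fell, Trib2, Cul4b and Rbx1 (median 0.22). The call of the latter (adjusted p = 0.0338) was lost with an estimated correlation (0.327), upper quartile scaling (0.0592) and each guide alone (0.055 and 0.0533). CDK inhibitors and p53 targets went both ways, with 6 of 15 higher and 3 lower in the vehicle comparison (adjusted p = 0.247), Cdkn1b at 0.79 ± 0.04 and Trp53inp1 at 2.01 ± 0.14 against Aen at -1.51 ± 0.07, or -1.09 (adjusted p = 0.167) with a joint knockout group. Of 9 adipogenic and lipid handling genes, 4 were higher and 3 lower in the IFN-gamma comparison (adjusted p = 0.769), with Cpt1a at -1.13 ± 0.06 and Lipe at -1.49 ± 0.09. Of 15 housekeeping genes, 6 were higher and 6 lower in vehicle (adjusted p = 0.952), with Pgk1 at 1.02 ± 0.03 and Gusb at -1.18 ± 0.05, and with a joint knockout group the call of Actb was lost (-0.52, adjusted p = 0.0542).

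Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were higher for 5 of 9 in the vehicle comparison (adjusted p = 0.202), with H1f2 at 2.14 ± 0.13. The call of H2ac18 among them was lost with a joint knockout group (adjusted p = 0.0661) and without control vehicle replicate 1 (0.0669) or 2 (0.0653) or sgRNA1 vehicle replicate 2 (1). Markers of other cell types were few among tested genes. Of 4 macrophage markers 3 were higher and 1 lower in vehicle (adjusted p = 0.202), with Cd14 at 0.72 ± 0.09. With a joint knockout group 3 of these calls were lost, Cd14 (0.75, adjusted p = 0.0723), Cd68 (1.77, adjusted p = 0.0934) and Mrc1 (-1.11, adjusted p = 0.112), and that of Mrc1 also without control vehicle replicate 1 (0.115). Of 4 fibroblast markers 4 were higher (adjusted p = 0.0445, but 0.235 with an estimated correlation), with Col6a1 at 1.34 ± 0.12. That call was lost with upper quartile scaling (0.0536), sgRNA1 alone (0.0751) and without control vehicle replicate 1 (0.0577). Of 3 endothelial markers 1, Tie1, was higher (list adjusted p = 0.664). The call of Tie1 was lost with DESeq2 (adjusted p = 0.0512), a joint knockout group (0.0654), and without control vehicle replicate 1 (0.159) or sgRNA2 vehicle replicate 1 (0.127).

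The 8 knockout-labelled libraries can be split into 4 and 4 in 35 ways. In a fit of those libraries to the 2 sides alone, the split by treatment called 3812 genes and the highest of the others, the split by guide, called 1660. Only the real split, 1 of 35, gave as many. The 35 splits take the libraries as separate samples that are interchangeable across guides, although the split by guide called 1660 genes. The share of 1 in 35 therefore does not exclude chance for the response of knockout-labelled cells to IFN-gamma. With the 2 libraries of each group kept together there are 3 splits, too few for a share under 0.05.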
